A study of Homo sapiens with 24 samples.

How the data were processed

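The series held 24 expression arrays of SW1222 cells, in 9 groups taken from the labels, with 3 arrays per group in the induction and shRNA experiments and 2 per group in the knockout experiment. Total RNA was extracted with Trizol and labelled with biotin by an Affymetrix protocol, per the labels. The deposited values are on the log2 scale and were produced by the authors with Partek 6.6 and RMA, per the submitters' processing notes. RMA corrects background, equalises the arrays by quantiles and summarises the probes of each set. The genome build behind the probe annotation is not given in the sources used here. The values ran from 1.56 to 12.5, array medians from 4.01 to 4.12 and array means from 4.42 to 4.44, as checked on the table. Replicate arrays correlated across genes at r = 0.987 to 0.994, where genes are not independent replicates. The first principal component (38.9% of the variance) separated the induction experiment from the others, so every comparison was kept within an experiment.

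The table had 20276 probe sets, of which 18062 carried 1 gene symbol, 1288 carried several and 926 were unnamed in the annotation given. For each of 17448 genes the probe set with the highest mean was tested, and 468 genes had more than 1. Probe sets with several symbols or none were left out. CA9, a HIF target, had no probe set of its own and was not analysed here. The comparisons were induced over control cells in 3D and in 2D, DPPA3 shRNA over control shRNA, each knockout clone and the mean of both over the scrambled guide, the difference of the induction effects between 3D and 2D, the difference between the clones, and the control line in 3D over 2D. One linear model with a coefficient per group was fitted with limma 3.58.1 in R 4.3.3, with moderated variances (15 residual and 9.81 prior degrees of freedom) and 2-sided tests. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison.

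The 22 gene lists (634 members, 583 measured), the comparisons, the alternatives and the rule for naming genes were fixed before the data were examined. The lists covered S phase and DNA replication, G2 and mitosis, hypoxia and HIF targets, p53 targets, cell-cycle inhibitors and quiescence, interferon-stimulated genes, germline and cancer-testis genes, pluripotency and early germ cell factors, imprinted genes, the DNA methylation machinery, Wnt targets and intestinal stem cells, absorptive enterocytes, and goblet and enteroendocrine cells. They also covered mesenchymal and fibroblast genes, leukocyte and endothelial genes, drug transport and metabolism, cholesterol synthesis, the unfolded protein and integrated stress response, ribosome biogenesis, oxidative phosphorylation, immediate early genes, and NF-kappaB and inflammatory targets. Each list was compared with all other genes by camera at its preset correlation of 0.01, adjusted over the 22 lists, then with a correlation estimated from the data, and tested by the rotation test fry. Counts of members are given over all genes and adjusted over the list alone.

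Genes were named by a rule. DPPA3 was always named. In the comparisons of induction in 3D and 2D, the knockdown and the mean of the clones, the 8 highest and 8 lowest log2 fold changes were named among genes that passed, whose arrays did not overlap between groups, whose higher group mean exceeded the median of all genes, and whose symbol was not of the LOC or LINC kind. For single clones, differences of effects and the control line, 4 per direction were named. From every list called by camera, the 3 members with the smallest p in its direction were named. HIF1A, UHRF1, DNMT1, MKI67, CDKN1A, VEGFA and LGR5 were named whatever their values.

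Fold changes of 8 pairs of comparisons were correlated across genes, and shared genes were counted against those that independent lists would share with 1-sided Fisher's exact tests (32 tests, Benjamini-Hochberg adjusted). Because both clones share their control arrays, the correlation and the covariance were simulated 100 times with unchanged clones. Runs of neighbouring genes were sought in the gene order of the NCBI RefSeq table given, among 8734 genes above the median level, as stretches where the running median over 21 genes exceeded a threshold, set so that 95% of 200 shuffled orders stayed below it along their whole length. The method was tested on simulated data with 200 changed genes. Changes of 1 log2 were recovered in 97.0% of genes for induction in 3D, 98.5% for the knockdown, 89.6% for C66 and 83.6% for the difference of effects, changes of 0.5 log2 in 50%, 50%, 36.4% and 10.6%. False calls were 7 of 172 for induction in 3D, 6 of 172 for the knockdown, 9 of 160 for C66, 9 of 172 for the mean of the clones and 9 of 139 for the difference of effects. The single shifted list was found and 0 other lists were called by camera. The simulated genes varied independently, so this could not show whether camera calls too many lists when members are correlated. All 6 planted runs were found and 0 where none was planted.

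The alternatives were cyclic loess, median centring, leaving out the 33.3% of genes with the lowest signal, testing every probe set, averaging probe sets, moderated variances with a trend and robust estimation, array weights, replicate number as a block, variances from a comparison's own arrays only, leaving out each array in turn, and camera with an estimated correlation. Added after seeing the data were leaving out a pair of arrays that deviated together, leaving out the genes of neighbour runs, and giving each clone a control array of its own. Where leaving out an array left 1 array in a group, the lone array was assumed to vary like the other groups.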

Results

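Gene expression was measured on 24 arrays of SW1222, an established human colorectal cancer cell line, in which the gene DPPA3 had been induced, knocked down or knocked out. DPPA3 encodes a small protein of early germ cells and oocytes that binds UHRF1, a factor needed to keep DNA methylation through replication. The arrays fell into 9 groups. Cells with doxycycline-induced DPPA3 and their control line were grown as Matrigel-embedded megacolonies, called 3D here, with 5 µg/ml doxycycline for 5 days, on 3 arrays per line. The same pair of lines was grown in 2D with the drug for 4 hours, again on 3 arrays per line. No arrays of the induced line without doxycycline were analysed here. Rises and falls with induction are therefore differences between the induced line and its control line. A response to DPPA3 cannot be told apart in them from a standing difference between the lines. A DPPA3 shRNA and a control shRNA had 3 arrays each in 3D. A line with a scrambled guide RNA and knockout clones C66 and C75 had 2 arrays each in 3D. All cultures were kept at 21% oxygen, so a difference in hypoxia genes did not come from a difference in the oxygen supplied. The 17448 genes tested had array medians between 4.01 and 4.12 on the log2 scale, and the number of arrays limited the precision. The median SE of a log2 fold change was 0.12 for 3 arrays against 3 and 0.15 for 2 against 2. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these arrays.

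The targeted gene was examined first, in every array. In the 18 arrays without the transgene, the DPPA3 signal lay between 2.55 and 3.47 log2, and 14.6% to 38.5% of all genes gave a lower signal, so it was at the dim end of the scale. With induction in 3D it read 3.77, 4.54 and 4.74, against 2.99, 2.59 and 2.97 in the control line. The log2 fold change was 1.502 (SE 0.31, adjusted p = 0.00251). With induction in 2D it read 4.73, 4.18 and 6.16, against 2.83, 3.27 and 3.47, a log2 fold change of 1.84 (adjusted p = 0.000475). Over control signals this dim, both values can understate the rise in RNA. The shRNA arrays read 2.71, 3.13 and 2.77 and their controls 2.80, 2.78 and 3.15, a log2 fold change of -0.04 (adjusted p = 0.9996). The knockout arrays read 2.55 and 2.82 in C66 and 3.19 and 2.89 in C75, against 2.68 and 3.03 in their control. The log2 fold change was -0.16 in C66 (adjusted p = 0.971) and 0.19 in C75 (adjusted p = 0.983). No loss of DPPA3 RNA was measurable at this signal, and a guide RNA can disrupt a gene without lowering its RNA, so the array neither shows nor excludes the knockdown and the knockouts.

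**Figure D1:**
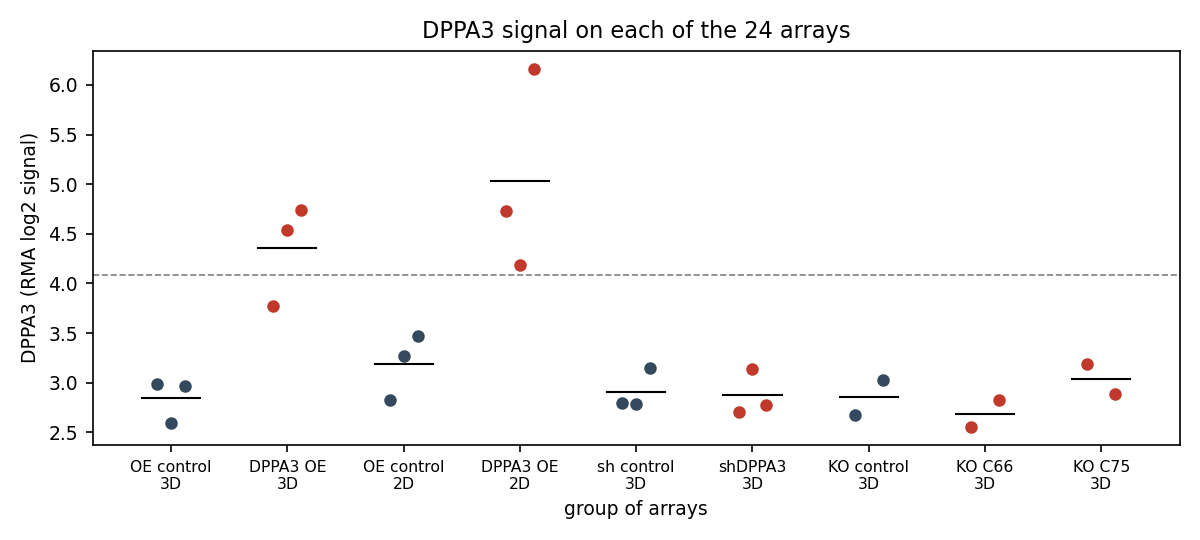
DPPA3 signal (log2) on each of the 24 arrays by group, with red points for arrays in which DPPA3 was altered, dark points for controls, black lines for group means and a dashed line at the median of all genes, 4.08. The 6 induced arrays lie between 3.77 and 6.16, above all 18 others, which lie between 2.55 and 3.47.

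With DPPA3 induced in 3D, genes of cell division were lower than in the control line, and 9 of 40 listed genes that respond to low oxygen were higher and 1 lower. The hypoxia list as a whole lost its call under the stricter test (adjusted p = 0.0752 with an estimated correlation). The comparison addresses the slow cell cycle and the HIF1A axis named in the study's title. MKI67, the proliferation marker, fell by 0.56 log2 (adjusted p = 9.95e-04), and DNMT1, the maintenance DNA methyltransferase, fell by 0.57 (adjusted p = 1.13e-04). LGR5, a marker of intestinal stem cells, rose by 0.59 (adjusted p = 0.00116), and VEGFA, an angiogenic growth factor and HIF target, rose by 0.56 (adjusted p = 0.0139). HIF1A itself had a log2 fold change of -0.12 (adjusted p = 0.788), UHRF1 of -0.19 (adjusted p = 0.704) and CDKN1A, a cell-cycle inhibitor, of 0.30 (adjusted p = 0.342), and none of these passed. The largest rises were in the receptor tyrosine kinase KIT (3.08 log2, adjusted p = 1.86e-11), the phosphodiesterase PDE3A (2.71), the stem cell glycoprotein OLFM4 (2.35), the creatine kinase CKB (2.24), the small Cajal body RNA SCARNA11 (2.03), STOML3 (1.99), LSAMP (1.88) and SBSPON (1.82). The largest falls were in the secreted phospholipase PLA2G2A (-3.27 log2, adjusted p = 5.32e-16), NELL2 (-3.08), the cystatin CST1 (-2.19), CYP4X1 (-2.03), the goblet cell gene SPINK4 (-1.86), the metalloproteinase inhibitor TIMP1 (-1.75), AKR1E2 (-1.69) and the uroplakin UPK1A (-1.495). That the 3 induced arrays did not overlap the 3 control arrays was a condition for naming these 16 genes. In all, 995 genes changed, 511 higher and 484 lower, 60 of them at least 2-fold. The count was 663 without induced replicate 3, 468 with the variance taken from these 6 arrays alone and 601 without genes in runs of shifted neighbours, described further on, to which AKR1E2 belongs. MKI67 did not pass with these 6 arrays alone (adjusted p = 0.0585), and VEGFA did not pass without induced replicate 1 (adjusted p = 0.0731) or control replicate 3 (adjusted p = 0.0715).

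Gene lists fixed beforehand were then compared with all other genes. The list of G2 and mitosis genes had a median log2 fold change of -0.37, with 51 of its 53 members below 0 (camera adjusted p = 1.69e-20; adjusted p = 0.00211 with an estimated correlation). Of these, 22 were lower after adjustment over all genes and 36 adjusted over the list alone. They included the kinesin KIF23 of cytokinesis (-0.64), the ubiquitin enzyme UBE2C of mitotic exit (-0.54) and GTSE1 (-0.95), which lies in a run of shifted neighbours. The S phase list had a median of -0.37 (camera adjusted p = 1.59e-15; adjusted p = 0.0190 with an estimated correlation). Its lower members numbered 15 of 41, or 26 with 2 higher adjusted over the list alone, and included the helicase BLM (-1.12), the histone chaperone NASP (-0.69) and WDR76 (-0.66). The hypoxia list had a median of 0.27 (camera adjusted p = 1.70e-09), a call lost under the stricter test (adjusted p = 0.0752 with an estimated correlation). Of its 40 members 9 were higher and 1, ANKRD37, was lower, against 17 and 1 adjusted over the list alone. The collagen-modifying enzymes P4HA1 (1.19) and PLOD2 (0.74) and the lactate dehydrogenase LDHA (0.75) led it, of which P4HA1 and LDHA lie in runs of shifted neighbours. Absorptive enterocyte genes had a median of 0.17 (camera adjusted p = 7.81e-06; adjusted p = 0.0190 with an estimated correlation), with 5 of 27 members higher and 1 lower, against 9 and 1 adjusted over the list alone. The chloride exchanger SLC26A3 (1.17), CEACAM7 (1.06) and CEACAM6 (0.77) led this list. Ribosome biogenesis genes had a median of -0.24, with 26 of 27 below 0 (camera adjusted p = 1.28e-07; adjusted p = 0.0201 with an estimated correlation). Only 3 members were lower, 4 adjusted over the list alone. PA2G4 (-0.37), UTP20 (-0.32) and MRTO4 (-0.50) each lost the call without 1 array, with adjusted p up to 0.0895, 0.248 and 0.252. For PA2G4 these arrays were induced replicate 3 or control replicate 1, for UTP20 induced replicates 1 or 3 or control replicates 2 or 3, and for MRTO4 any except control replicate 3. Interferon-stimulated genes had a median of 0.12 (camera adjusted p = 0.00461; adjusted p = 0.0750 with an estimated correlation), with 3 of 32 members higher both over all genes and adjusted over the list alone. HERC6 (0.62) passed in every alternative, while ISG15 (0.50) and IFIT2 (0.39) lost the call without 1 array, with adjusted p up to 0.190 and 0.182. For ISG15 these arrays were induced replicates 1 or 2 or control replicates 1 or 2, and for IFIT2 any except induced replicate 2. The rotation test fry, which asks whether the genes of a list move one way and does not compare them with other genes, passed for all 6 of these lists (adjusted p up to 0.00387).

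The other 16 lists did not pass in 3D. The camera adjusted p was 0.271 for cell-cycle inhibitors and quiescence, 0.658 for p53 targets, 0.319 for the DNA methylation machinery, 0.934 for germline and cancer-testis genes, 0.515 for pluripotency and early germ cell factors and 0.515 for imprinted genes. It was 0.546 for Wnt targets and intestinal stem cells, 0.194 for goblet and enteroendocrine cells, 0.194 for cholesterol synthesis, 0.494 for drug transport and metabolism and 0.0594 for the unfolded protein and integrated stress response. It was 0.644 for oxidative phosphorylation, 0.192 for immediate early genes, 0.494 for NF-kappaB and inflammatory targets, 0.934 for mesenchymal and fibroblast genes and 0.644 for leukocyte and endothelial genes.

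**Figure D2:**
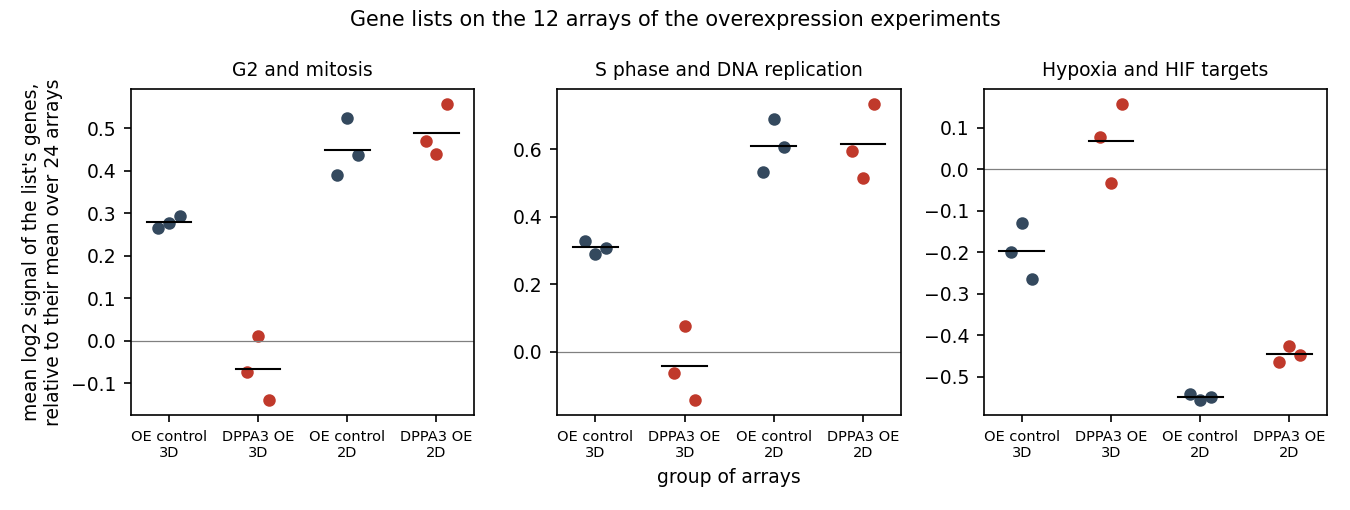
Mean score of the G2 and mitosis, S phase and hypoxia lists (log2, relative to the mean of each gene over all arrays) on each of the 12 arrays of the induction experiment, red for induced, dark for control, with black lines for means. In 3D the G2 and mitosis score was -0.07, 0.01 and -0.14 in the induced arrays and 0.27, 0.28 and 0.29 in the controls.

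After 4 hours in 2D, a comparison meant to show short-term effects, 3 of 22 listed genes of Wnt signalling and intestinal stem cells and 5 of 29 of drug handling were higher. As groups, neither list kept its call (adjusted p = 0.401 and 0.264 with an estimated correlation). Here too the induced line is set against its control line, and a standing difference between them could give such values without a response to DPPA3. The stem cell gene OLFM4 rose by 3.81 log2 (adjusted p = 1.43e-15), SMOC2 by 1.77 and LGR5 by 1.02 (adjusted p = 2.08e-06). The drug efflux pump ABCB1 rose by 1.20 (adjusted p = 7.75e-08), the aldehyde dehydrogenase ALDH1A1 by 0.69 and the thymidylate synthase TYMS, the target of fluorouracil, by 0.60. PDE3A (2.62), the iron-binding protein LCN2 (1.52), CA8 (1.51), CKB (1.41) and the phosphate transporter ANKH (1.33) completed the largest rises beside DPPA3. The largest falls were in NELL2 (-3.40 log2, adjusted p = 5.36e-12), TIMP1 (-1.68), PLA2G2A (-1.56), AKR1E2 (-1.21), UPK1A (-1.20), RNF157 (-1.18), CYP4X1 (-1.18) and PYGO1 (-1.14). MKI67 (-0.05, adjusted p = 0.901), DNMT1 (-0.08, adjusted p = 0.801), VEGFA (-0.13, adjusted p = 0.773), HIF1A (-0.11, adjusted p = 0.823), UHRF1 (0.21, adjusted p = 0.685) and CDKN1A (0.03, adjusted p = 0.963) did not pass. In all, 546 genes changed, 327 higher and 219 lower, 37 of them at least 2-fold. The count was 314 with the variance taken from these 6 arrays alone and 210 without genes in runs of shifted neighbours. Those runs hold ABCB1, ANKH, AKR1E2, P4HA1, LDHA, HMGCS1 and CYP51A1.

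None of the 4 lists called in 2D kept its call with an estimated correlation. Cholesterol synthesis had a median of 0.27 (camera adjusted p = 3.98e-06; adjusted p = 0.177 with an estimated correlation), with 5 of 18 members higher, 10 adjusted over the list alone, led by HMGCS1 (0.97), CYP51A1 (0.63) and the sterol carrier STARD4 (0.60). Wnt targets and intestinal stem cells had a median of 0.08 (camera adjusted p = 0.00213; adjusted p = 0.401 with an estimated correlation), from OLFM4, SMOC2 and LGR5 alone, 3 of 22 members on both adjustments. Drug transport and metabolism had a median of 0.05 (camera adjusted p = 0.0166; adjusted p = 0.264 with an estimated correlation), with 5 of 29 members higher on both. The hypoxia list had a median of 0.14 (camera adjusted p = 0.0447; adjusted p = 0.544 with an estimated correlation), with P4HA1 (0.93) and LDHA (0.64) as its only higher members on both adjustments. This call ended without induced replicate 2 (adjusted p = 0.158) or without control replicates 1, 2 or 3 (adjusted p = 0.0576, 0.0925 and 0.0621), with a median of 0.0847 without control replicate 2. Fry passed for the first 3 of these lists (adjusted p up to 0.00233) and not for the hypoxia list (adjusted p = 0.287; adjusted p = 0.544 with an estimated correlation). The G2 and mitosis list had a median of 0.03 (adjusted p = 0.572) and the S phase list of -0.06 (adjusted p = 0.815).

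The effects of induction in the 2 cultures were then compared gene by gene. Across 17448 genes, which are not independent replicates, the fold changes in 3D and 2D correlated with Pearson's r = 0.455 and Spearman's rho = 0.267. NELL2, PLA2G2A, TIMP1, UPK1A and CYP4X1 were lower, and OLFM4, PDE3A, CKB and LGR5 higher, in both. Both comparisons set the same lines against each other, so a standing difference between the lines would be shared as well. In all, 171 genes were higher in both, where independent lists would share 9.58, and 127 were lower in both, where 6.07 would be shared. The adjusted p was 1.74e-179 and 2.46e-142 by Fisher's exact test, 1-sided, over 32 tests on 8 pairs of comparisons. Many of these genes lie in runs of shifted neighbours, described further on, and are not independent. Outside all runs 78 were higher in both, where 4.29 would be shared, and 31 lower, where 2.02 would be. No gene was higher in 3D and lower in 2D by limma, while 3 genes, SNORA67, SRRD and ASB4, were lower in 3D and higher in 2D, of which SRRD and ASB4 were chosen after their values were seen. Independent lists would share 6.41 and 9.07. The difference of the effects passed for 42 genes, 18 with a higher value in 3D and 24 with a lower one. The effect in 3D minus that in 2D was 2.02 log2 for KIT (adjusted p = 1.96e-04), 1.39 for FAM13A, -1.71 for PLA2G2A (adjusted p = 3.31e-06), -1.55 for SMOC2 and -1.46 for OLFM4. CEACAM7 (1.33), RNASE2 (1.12) and SNORA67 (-1.38) passed too, but lost the call without 6, 9 and 7 single arrays, with adjusted p up to 0.0860, 0.0853 and 0.0860. The G2 and mitosis list differed by a median of -0.39 (camera adjusted p = 1.41e-21; adjusted p = 0.00162 with an estimated correlation), with 2 of 53 members lower, 22 adjusted over the list alone. The S phase list differed by -0.37 (camera adjusted p = 1.75e-14; adjusted p = 0.0270 with an estimated correlation), with 1 of 41 lower, 10 adjusted over the list alone. Absorptive enterocyte genes differed by 0.07 (camera adjusted p = 9.17e-05; adjusted p = 0.0270 with an estimated correlation), with 3 of 27 higher, 5 adjusted over the list alone. Fry passed for these 3 lists (adjusted p up to 0.00750). Culture and time under the drug changed together, so their parts in the difference cannot be told apart. The count of 42 became 11, 70 and 19 without induced replicates 1, 2 and 3 in 3D, and 24, 11 and 25 without the 3D control replicates. It became 19, 22 and 23 without induced replicates 1, 2 and 3 in 2D, and 22 without the 2D control replicate 1. With the variance taken from these 12 arrays alone it was 7.

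**Figure D3:**
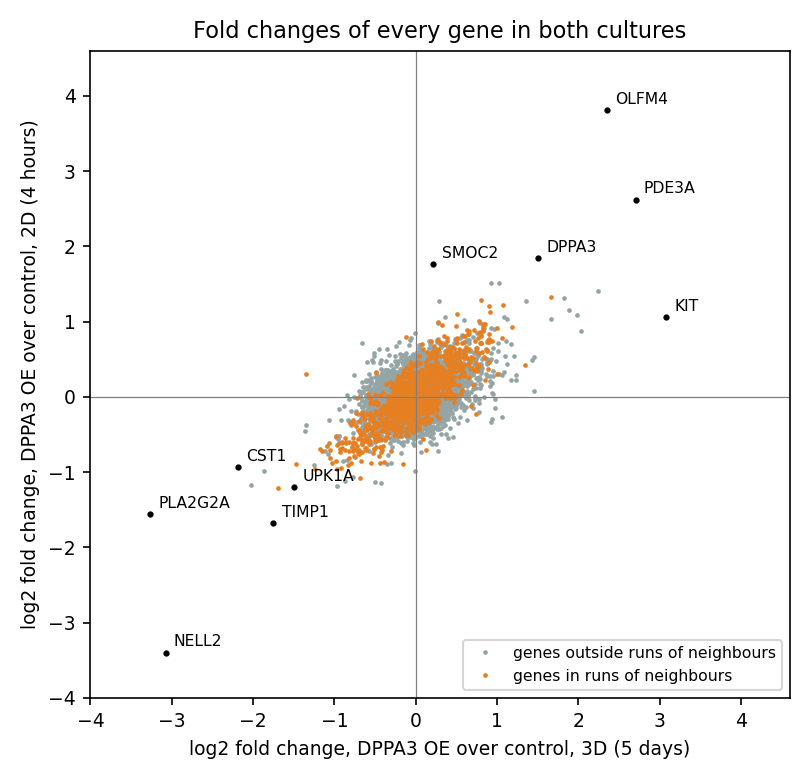
Log2 fold change of induced over control cells in 2D (vertical axis) against that in 3D (horizontal axis) for each gene, with genes in runs of shifted neighbours in orange. The fold changes correlated across genes at r = 0.455 (rho = 0.267), and of genes that passed in both, 0 were higher in 3D and lower in 2D and 3 were lower in 3D and higher in 2D.

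The control line itself differed between the 3D and 2D cultures, which gives the background to the induced lines. The hypoxia genes NDRG1 (1.54 log2, adjusted p = 2.33e-06) and VEGFA (1.12) and the lipoprotein receptor VLDLR (1.39) were higher in 3D. The hypoxia list as a whole was called by camera only with the preset correlation (adjusted p = 0.0919 with an estimated correlation). CST1 (2.06) and the trypsin inhibitor SPINK1 (1.34) were higher too. The xenobiotic-metabolising enzyme CYP1A1 was lower by the most (-3.23, adjusted p = 4.57e-11), with the reductases AKR1C2 (-1.77) and AKR1B10 (-0.90) and the histone H2BC13 (-0.92). In all, 1361 genes differed, 859 higher and 502 lower. Ribosome biogenesis genes were lower (median -0.37, camera adjusted p = 5.61e-13; adjusted p = 0.00636 with an estimated correlation), with 13 of 27 members lower, 18 adjusted over the list alone. The hypoxia list had a median of 0.19 (camera adjusted p = 8.19e-09; adjusted p = 0.0919 with an estimated correlation), with 13 of 40 members higher, 14 adjusted over the list alone. The S phase list was lower (median -0.35, camera adjusted p = 1.59e-10; adjusted p = 0.0873 with an estimated correlation), with 17 of 41 members lower and 1 higher, 23 and 1 adjusted over the list alone. The G2 and mitosis list was lower (median -0.23, camera adjusted p = 8.94e-06; adjusted p = 0.0919 with an estimated correlation), with 10 of 53 lower and 3 higher, 23 and 3 adjusted over the list alone. Wnt targets and intestinal stem cells (median 0.15, adjusted p = 0.225 with an estimated correlation), the unfolded protein and stress response (0.07, adjusted p = 0.0919 with an estimated correlation), goblet and enteroendocrine cells (0.07, adjusted p = 0.0873 with an estimated correlation) and immediate early genes (-0.14, adjusted p = 0.190 with an estimated correlation) were called with the preset correlation alone. Fry passed for all 8 lists (adjusted p up to 0.0131). Culture and time under the drug changed together here too. The count of genes was 875 without the 3D control replicate 2, 905 without the 2D control replicate 3, and 562 with the variance taken from these 6 arrays alone.

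The knockdown, which asks what loss of DPPA3 does in 3D, changed few genes. The protease inhibitor gene A2ML1 rose by 1.41 log2 (adjusted p = 3.90e-06), the prostaglandin receptor PTGDR by 0.98 (adjusted p = 7.66e-05), the phospholipase PLA2G2A by 0.79 (adjusted p = 0.00120) and the adhesion protein CEACAM5 by 0.72 (adjusted p = 1.02e-04). The lipoprotein lipase LPL fell by 1.11 (adjusted p = 1.02e-04), MYL3 by 0.74 (adjusted p = 9.59e-04), the tight junction protein CLDN1 by 0.72 (adjusted p = 0.00287) and LY6G6D by 0.71 (adjusted p = 3.35e-04). RPE65 (0.97), GCNT3 (0.73), CCDC28A (-0.69), CTSS (-0.64), APLF (-0.60) and RNASE1 (-0.52) passed but each lost the call without single arrays, with adjusted p up to 0.317. These were any of the 6 arrays for CCDC28A and RNASE1, any except control replicate 3 for APLF, control replicates 1 or 2 or knockdown replicates 1 or 3 for CTSS, control replicates 1 or 3 or knockdown replicates 1 or 2 for RPE65, and control replicates 2 or 3 or knockdown replicate 1 for GCNT3. HIF1A (0.01), UHRF1 (0.09), DNMT1 (0.06), MKI67 (0.07) and CDKN1A (0.12) had adjusted p = 0.9996, and VEGFA (-0.29, adjusted p = 0.914) and LGR5 (-0.26, adjusted p = 0.820) did not pass. In all, 15 genes changed, 6 higher and 9 lower. The count was 8 without knockdown replicate 1, 9 without control replicate 2 and 26 with array weights, and 917 genes had an unadjusted p under 0.05.

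The preset camera test called 6 lists in the knockdown, and none kept the call with an estimated correlation or with the rotation test fry. The hypoxia list was lower (median -0.15, camera adjusted p = 9.78e-07; adjusted p = 0.226 with an estimated correlation), with 33 of 40 members below 0. Its members CA12 (-0.51, adjusted p = 0.0908), ANKRD37 (-0.56, adjusted p = 0.425) and HK2 (-0.39, adjusted p = 0.618) did not pass, and 2 members were lower adjusted over the list alone. Without knockdown replicate 3 the median of the list was -0.0681 (adjusted p = 0.0220). The S phase list had a median of 0.08 (camera adjusted p = 0.00209; adjusted p = 0.304 with an estimated correlation) and the G2 and mitosis list of 0.04 (camera adjusted p = 0.00650; adjusted p = 0.252 with an estimated correlation). No member of either passed in limma over all genes or adjusted over the list alone. The S phase call ended without control replicate 3 (median 0.0444, adjusted p = 0.0682) and the G2 and mitosis call without control replicate 1 (median 0.07, adjusted p = 0.102). Without knockdown replicate 3 the S phase median was 0.13 and the G2 and mitosis median 0.10, and the latter was 0.07 without control replicate 2 or knockdown replicate 1. Absorptive enterocyte genes had a median of 0.05 (camera adjusted p = 0.00864; adjusted p = 0.226 with an estimated correlation), with CEACAM5 as the higher member, 3 adjusted over the list alone. Leukocyte and endothelial genes had a median of 0.07 (camera adjusted p = 0.0387; adjusted p = 0.226 with an estimated correlation). The unfolded protein and stress response list had a median of -0.05 (camera adjusted p = 0.0387; adjusted p = 0.251 with an estimated correlation), and no member of these 2 lists passed on either adjustment.

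The knockout clones shared few changes. In both clones the actin-binding protein gene CNN3 fell (-1.03 in C66 and -0.73 in C75), as did the neuromedin receptor NMUR2 (-0.92 and -1.42), the transcriptional regulator ID1 (-0.68 and -1.04), the galectin LGALS1 (-0.85 and -0.86), BBX (-0.84 and -0.77), the glutamate transporter SLC1A3 (-0.73 and -0.86) and ADPRM (-0.56 and -0.58). LY6G6D (0.85 and 0.53) and TRIM31 (0.76 and 0.82) rose in both. These 9 genes compare with 0.209 higher and 0.472 lower that independent lists would share (adjusted p = 0.0294 and 2.41e-06 by Fisher's exact test). The clones share their control arrays, so their lists are not independent and these p-values do not test a shared response. The count of 9 became 1 and 4 without control replicates 1 and 2, 4 and 3 without C66 replicates 1 and 2, and 4 without C75 replicate 2. Another 8 genes went opposite ways, among them TIMP1 (1.42 in C66 and -1.12 in C75), UPK1A (1.10 and -1.75), NELL2 (0.94 and -1.81) and GABRA2 (-1.10 and 1.42). Of these, 5 were higher in C66 and lower in C75, where independent lists would share 0.732, and 3 were lower and then higher, where 0.135 would be shared (adjusted p = 0.00191 and 8.51e-04 by Fisher's exact test). Outside the naming rule, LGALS1, BBX, SLC1A3 and ADPRM were chosen after their values were seen. TIMP1 lies in a run of shifted neighbours. Both clones were set against the same 2 control arrays, so their fold changes correlate by construction: r was 0.350 across genes, against 0.501 simulated with no effect, and the covariance was 0.0146 against 0.0126. With a control array of its own for each clone, a division chosen after seeing the data, r was 0.110 and 0.0637 in the 2 assignments and the clones shared 2 and 1 genes changed the same way.

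Each clone had more changes of its own. In C66, 250 genes changed, 152 higher and 98 lower, with the calcium-binding protein S100A4 (1.66), SLC26A3 (1.53), the sodium-proton exchanger SLC9A4 (1.45) and TIMP1 highest and SPINK1 (-2.28), HAVCR1 (-1.77), KIT (-1.38) and IL37 (-1.36) lowest. In C75, 108 changed, 24 higher and 84 lower, with GABRA2, SNORA6 (1.14), MUC12 (1.14) and the chromatin organiser SATB1 (1.02) highest and CST1 (-2.34), NELL2, UPK1A and PLA2G2A (-1.67) lowest. MUC12 lost the call without control replicate 1 (adjusted p = 0.0621) or C75 replicate 2 (adjusted p = 0.217). For the mean of the clones 56 genes passed, 25 higher and 31 lower, with SPINK1 (-1.39, adjusted p = 1.09e-04), NMUR2 (-1.17, adjusted p = 2.39e-04), PLA2G2A (-1.07, adjusted p = 6.88e-05) and CNN3 (-0.88, adjusted p = 6.88e-05) passing whichever array was left out. Of these, SPINK1 passed in C66 but not in C75 (-0.51, adjusted p = 0.425). PLA2G2A passed in C75 but not in C66 (-0.47, adjusted p = 0.123). ID1 (-0.86) did not pass without control replicate 1 (adjusted p = 0.0884), and PQBP1 (0.89), in a run of shifted neighbours, did not pass without control replicate 2 (adjusted p = 0.262). LGR5 passed (-0.56, adjusted p = 0.0347) but lost the call without 5 of the 6 arrays, all except C75 replicate 1, and its log2 fold change was -1.16 in C66 and 0.04 in C75. For the mean, SNORA6 (0.92), SLC26A3 (0.87), CES1 (0.81), RP2 (0.80), EBP (0.80), TRIM31 (0.79), CYBRD1 (0.79), FAM3B (-1.04), KIT (-0.98) and IL37 (-0.92) passed too (adjusted p from 0.00864 to 0.0479). Each lost the call without single arrays, and only TRIM31 among them passed in both clones. RP2 and EBP lie in a run of shifted neighbours. DPPA3 (0.01), HIF1A (-0.03), UHRF1 (0.10), DNMT1 (0.00), MKI67 (0.07), CDKN1A (-0.06) and VEGFA (0.05) had adjusted p from 0.960 to 0.999. The counts for C66, C75 and the mean were 546, 256 and 248 with array weights, and 164 in C75 and 104 for the mean with the variance taken from the knockout arrays alone. Without control replicates 1 and 2 the counts were 120 and 89 in C66, 38 and 67 in C75, and 5 and 9 for the mean. Without replicates 1 and 2 of the clone itself they were 119 and 116 in C66 and 66 and 47 in C75, and for the mean 25 and 15 without those of C66 and 34 and 11 without those of C75.

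Few lists moved in the clones. In C75 ribosome biogenesis genes were higher, with all 27 above 0 (median 0.20, camera adjusted p = 2.76e-07; adjusted p = 0.0351 with an estimated correlation). No member passed in limma over all genes, and 1 did adjusted over the list alone. Goblet and enteroendocrine genes were lower in C75 (median -0.13, camera adjusted p = 0.00260; adjusted p = 0.0225 with an estimated correlation) and for the mean of the clones (median -0.13, camera adjusted p = 0.00682; adjusted p = 0.0264 with an estimated correlation). Their leading members for the mean, MUC2 (-0.32, adjusted p = 0.169), SPINK4 (-0.60, adjusted p = 0.283) and ZG16 (-0.42, adjusted p = 0.297), did not pass over all genes, and 1 member was lower adjusted over the list alone. In C66 the S phase list was lower (median -0.16, camera adjusted p = 0.00176; adjusted p = 0.539 with an estimated correlation), with 1 of 41 members lower on both adjustments. This call ended without control replicate 1 (median -0.10, adjusted p = 0.0501). Absorptive enterocyte genes were higher in C66 (median 0.05, camera adjusted p = 0.00603; adjusted p = 0.187 with an estimated correlation), with 5 of 27 higher and 1 lower, 8 and 2 adjusted over the list alone. Fry passed for each of these except the S phase list in C66 (adjusted p = 0.212; adjusted p = 0.539 with an estimated correlation), with adjusted p = 0.0259 for the absorptive list in C66 and up to 0.00563 for the others. For the mean of the clones the hypoxia list had a median of -0.01 (adjusted p = 0.172), the G2 and mitosis list of -0.05 (adjusted p = 0.172) and the S phase list of -0.07 (adjusted p = 0.111). In C75 the hypoxia list had a median of -0.0857 (camera adjusted p = 0.0800), and it was called lower there with the replicate number as a block. Without control replicate 2 the hypoxia list was called lower in C66 (-0.11, adjusted p = 0.0411), in C75 (-0.17, adjusted p = 2.96e-04) and for the mean (-0.16, adjusted p = 0.00107), and the S phase list for the mean (-0.14, adjusted p = 0.0401). The hypoxia list was called lower also without C75 replicate 1, in C75 (-0.19, adjusted p = 0.00150) and for the mean (-0.05, adjusted p = 0.0403), and without C66 replicate 1 for the mean (-0.06, adjusted p = 0.0289).

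**Figure D4:**
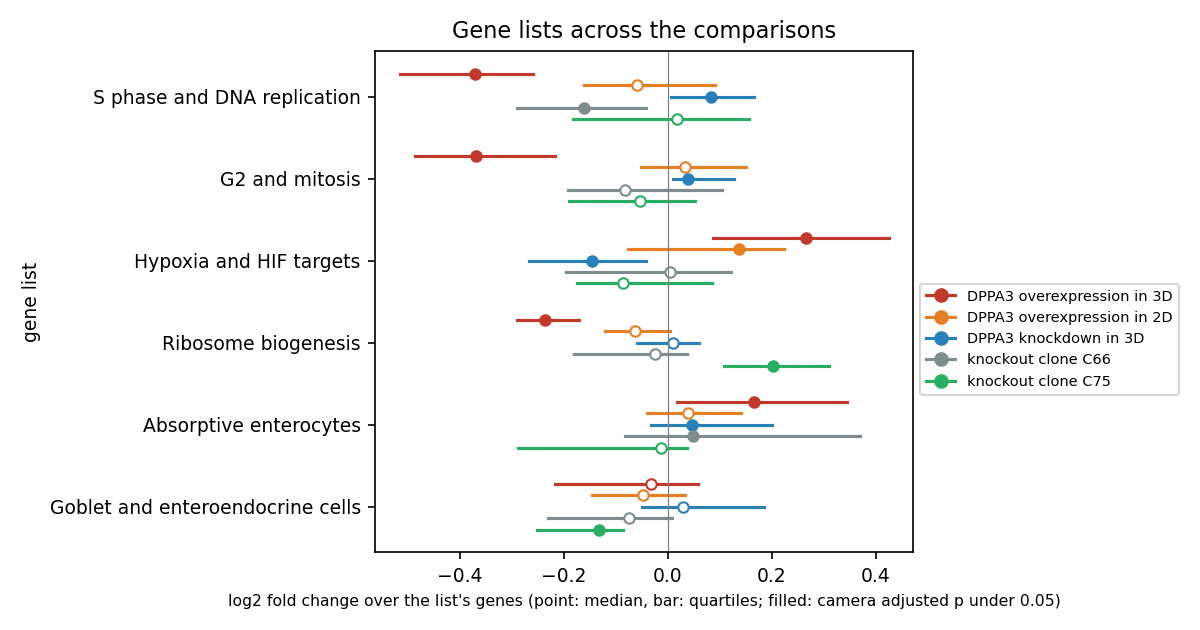
Median log2 fold change (points) and quartiles (bars) of the members of 6 gene lists in 5 comparisons, filled where camera's adjusted p with the preset correlation was under 0.05. The G2 and mitosis list had a median of -0.37 with induction in 3D, 0.03 in 2D and 0.04 in the knockdown.

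Gain and loss of DPPA3 were compared to see whether they moved genes in opposite directions. CLDN1, LY6G6D, MYL3, CTSS and APLF rose with induction in 3D (by 0.55, 1.01, 0.61, 1.09 and 0.48) and fell in the knockdown. These 5 genes compare with 0.264 that independent lists would share (adjusted p = 1.10e-05 by Fisher's exact test), of which CTSS and APLF, like RPE65, RNASE1 and GCNT3 among the genes that follow, lost the knockdown call without single arrays. PLA2G2A (-3.27 and 0.79) and PTGDR (-0.50 and 0.98) were lower with induction and higher in the knockdown, where 0.166 genes would be shared (adjusted p = 0.0190 by Fisher's exact test). Another 3 genes went the same way in both, and 1 did without knockdown replicates 1 or 2 or shRNA control replicate 1. RPE65 was higher (0.62 and 0.97), where 0.176 genes would be shared (adjusted p = 0.218 by Fisher's exact test). LPL (-0.67 and -1.11) and RNASE1 (-0.50 and -0.52) were lower, where 0.2497 would be shared (adjusted p = 0.0370 by Fisher's exact test). With induction in 2D, CLDN1 (0.62), LY6G6D (0.71), MYL3 (0.55) and CTSS (0.54) were higher too, 4 genes where 0.169 would be shared with those lower in the knockdown (adjusted p = 5.67e-05 by Fisher's exact test). PLA2G2A (-1.56) and CEACAM5 (-0.72) were lower in 2D and higher in the knockdown, where 0.0753 would be shared (adjusted p = 0.00485 by Fisher's exact test), and 0 genes went the same way by limma, which gave 917 genes at an unadjusted p under 0.05 in the knockdown. The count was 2 without the 2D induced replicate 2, and 1 without the 2D control replicate 2, shRNA control replicate 3 or knockdown replicate 1. Against the direction of the knockdown, LY6G6D rose in both clones (0.85 and 0.53), MYL3 rose in C66 (0.69), PTGDR fell in C66 (-0.92), A2ML1 fell in C66 (-1.13) and PLA2G2A fell in C75 (-1.67). The 4 that passed in C66 compare with 0.0337 higher in the knockdown and lower in the clone and 0.0784 the other way (adjusted p = 0.00114 and 0.00521 by Fisher's exact test). In the same order, the 2 in C75 compare with 0.0289 and 0.0124 (adjusted p = 0.0415 and 0.0207 by Fisher's exact test). In the direction of the knockdown, A2ML1 (1.01) and GCNT3 (0.81) rose in C75, where 0.00825 genes would be shared (adjusted p = 8.67e-05 by Fisher's exact test), and PTGDR had 0.59 in C75 (adjusted p = 0.0526). The 2 genes became 4 without shRNA control replicate 1, 1 without shRNA control replicate 2 or knockdown replicate 1, and 0 by limma without knockout control replicate 2 or C75 replicate 1. Across all genes the fold changes of induction in 3D correlated with those of the knockdown at r = -0.0590, of C66 at r = 0.00174 and of C75 at r = 0.102 (0.00418 without the 3D control replicate 3). Induction in 2D correlated with the knockdown at r = 0.00222. Against C66, 39 genes that passed in both went opposite ways, 17 higher with induction and 22 lower, where 2.87 and 4.22 would be shared (adjusted p = 2.15e-08 and 1.79e-09 by Fisher's exact test). Another 27 went the same way, 15 higher and 12 lower, where 4.45 and 2.72 would be shared (adjusted p = 1.19e-04 and 6.02e-05 by Fisher's exact test). These 27 became 15 and 13 without knockout control replicates 1 and 2, and 12 and 14 without C66 replicates 1 and 2. Against C75, 6 genes were higher with induction and lower in the clone, 1 was lower and then higher, and 4 were higher in both, where 2.46, 0.666 and 0.703 would be shared (adjusted p = 0.0510, 0.629 and 0.00913 by Fisher's exact test). Another 46 genes were lower in both, where independent lists would share 2.33 (adjusted p = 1.34e-48 by Fisher's exact test), among them PLA2G2A, CST1, NELL2, UPK1A and TIMP1. Of these, 30 lie in runs of shifted neighbours, described further on. Genes of a run shift together, so the test counts as independent genes that are not. Outside all runs 16 genes were lower in both, where 0.775 would be shared. Some genes shared with C66, such as TIMP1, lie in runs too. The 50 genes changed the same way became 19 and 31 without knockout control replicates 1 and 2, and 30 and 23 without C75 replicates 1 and 2.

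Part of these differences lay in long runs of neighbouring genes that shifted together. Runs were sought among 8734 brighter genes in chromosomal order as stretches where the running median over 21 genes exceeded a threshold set from shuffled orders. Induction in 3D had 8 runs and induction in 2D had 12, C66 and C75 had 5 each, the knockdown had 3 and the control line between cultures had 1. The runs of the induced line held 8.78% of genes, with 298 of the 995 genes changed in 3D and 246 of the 546 changed in 2D. The runs of the clones held 6.11% of genes, with 99 of the 250 changed in C66 and 46 of the 108 changed in C75. The runs were found from these same fold changes, so a larger share of changed genes inside them is built in. The shares only describe how many changed genes lie there. The widest fall in 3D spanned the genes from ZMYND11 to CCAR1 (median -0.50 over 105 brighter genes), and these genes had a median of -0.45 in 2D and -0.42 in C75 but 0.10 in C66. In C66 the genes from POLA1 to MAGED2, which include TIMP1, PQBP1, RP2 and EBP, had a median of 0.56. Outside all runs the fold changes of induction in 3D and 2D correlated at r = 0.353 across genes. The end genes of these runs were chosen after their values were seen.

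**Figure D5:**
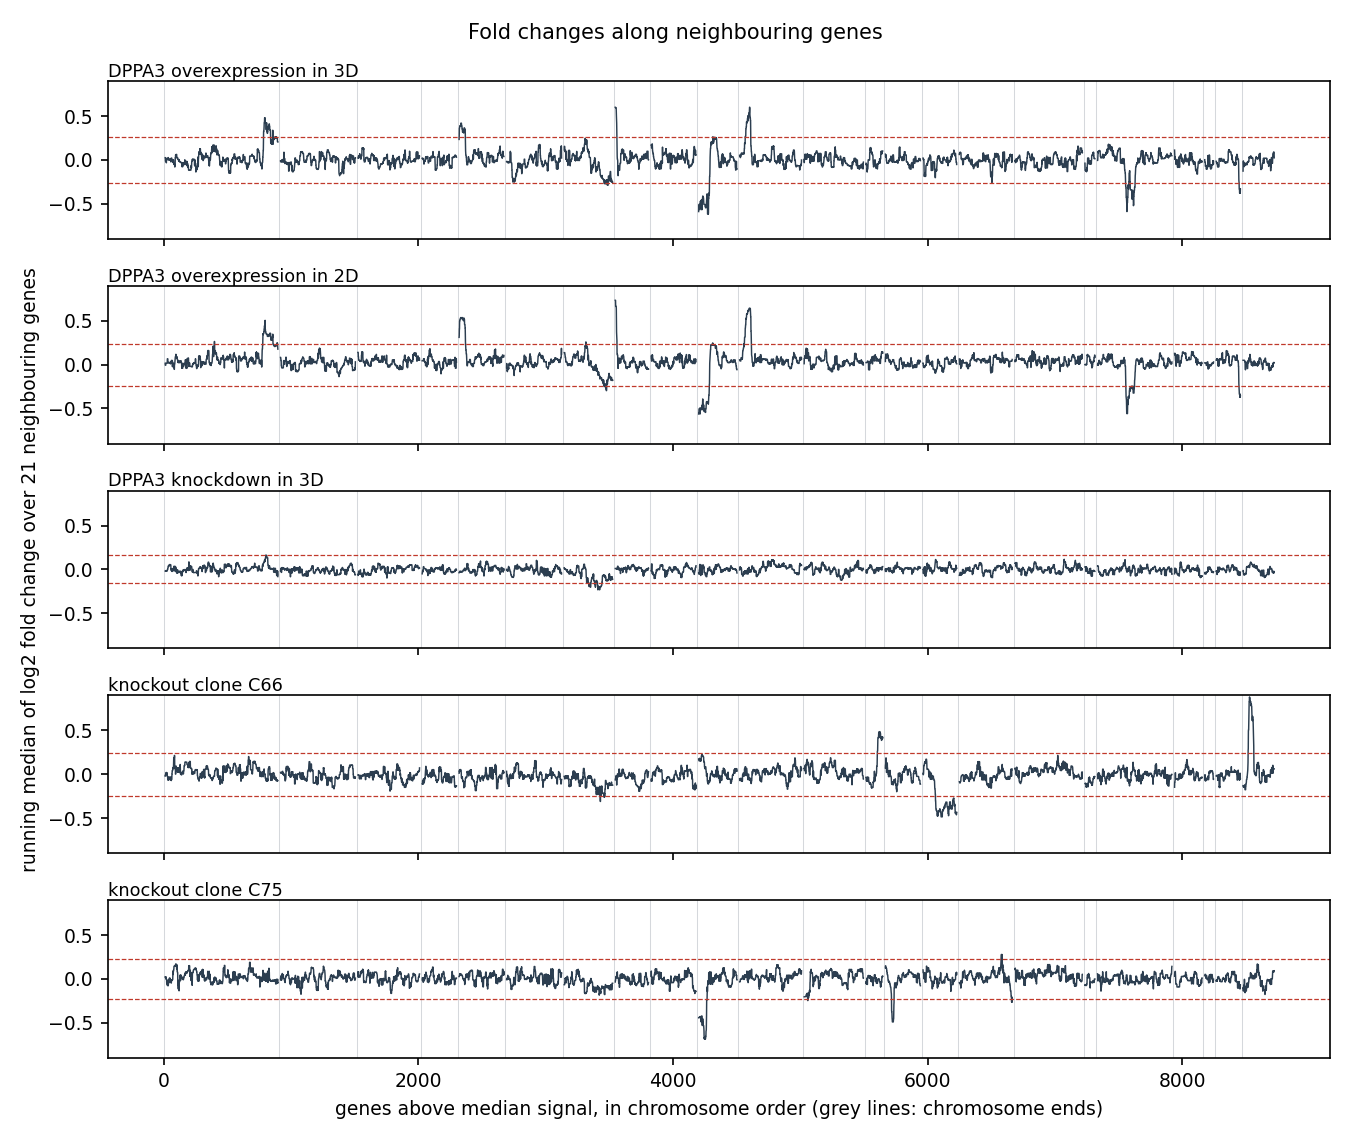
Running median of log2 fold change over 21 neighbouring genes in chromosomal order, for 5 comparisons, with dashed lines at the threshold set from shuffled orders. Induction in 3D crossed it in 8 runs and in 2D in 12, with the run from ZMYND11 lower in both and in C75.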

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

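The tests of the neighbour runs, of the shared run, of the direction of genes shared with C66 and of the genes lower in both the induced line and C75 were chosen after those results had been seen, and the tests of the cell-cycle lists without run genes and without a pair of arrays use alternatives added after seeing the data, while the counts over other splits were planned.

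The effect of induction differed between 3D and 2D for 42 genes by a test of the difference itself. The difference, 3D minus 2D in log2, was 2.02 for KIT, 1.39 for FAM13A, 1.33 for CEACAM7, 1.12 for RNASE2, 0.72 for PYGO1, -1.38 for SNORA67, -1.46 for OLFM4, -1.55 for SMOC2 and -1.71 for PLA2G2A. The medians of lists that differed by camera were -0.39 for G2 and mitosis, -0.37 for S phase, -0.19 for Wnt targets and intestinal stem cells, -0.16 for cholesterol synthesis and -0.16 for ribosome biogenesis. They were 0.0740 for absorptive enterocytes, 0.11 for immediate early genes, 0.14 for hypoxia and 0.21 for cell-cycle inhibitors. With an estimated correlation only G2 and mitosis, S phase and absorptive enterocytes kept their calls among these 9. The rotation test fry passed for 6 of them, and not for hypoxia (adjusted p = 0.231), cell-cycle inhibitors (0.0592) and cholesterol synthesis (0.0848). Of 100 relabellings of arrays within each culture, 11, the real one included, gave at least 42 genes, and the highest other gave 536. The 10 others kept the true groups in 1 culture, 5 in 3D and 5 in 2D, and mixed only the other. Such relabellings still hold the effect of the kept culture, so they do not stand for the absence of a difference of effects. The test therefore cannot decide on chance, which is neither shown nor excluded. The 80 relabellings mixed in both cultures gave at most 2 genes.

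The clones differed from each other in 506 genes by a direct test, more than either differed from the control. The difference, C75 minus C66 in log2, was 2.51 for GABRA2, 2.13 for A2ML1, 1.82 for HAVCR1, 1.77 for SPINK1, 1.499 for SATB1, 1.21 for LGR5, 0.88 for IL37, 0.87 for MUC12 and 0.80 for KIT. It was -2.84 for UPK1A, -2.74 for NELL2, -2.71 for PCP4, -2.54 for TIMP1, -2.08 for CST1, -1.88 for SLC9A4, -1.66 for S100A4, -1.32 for SLC26A3 and -1.20 for PLA2G2A. It was -0.85 for EBP, -0.78 for PQBP1, -0.75 for CYBRD1, -0.72 for RP2 and -0.71 for CES1. List medians differed by 0.30 for ribosome biogenesis, -0.17 for absorptive enterocytes and 0.17 for S phase, of which S phase lost its call with an estimated correlation (adjusted p = 0.587) and did not pass with fry (0.236), while the other two did. The count was 263 and 270 without C66 replicates 1 and 2, and 269 and 259 without C75 replicates 1 and 2.

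For the other counts, 3 arrays against 3 make 10 splits, too few for a share under 0.05. The real split, 1 of the 10, gave 995 genes for induction in 3D (highest other 2), 546 for induction in 2D (highest other 2), 15 for the knockdown (highest other 0 by limma, with 917 genes at an unadjusted p under 0.05 in the real split) and 1361 for the control line in 3D over 2D (highest other 0).

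The first pattern weighed is the runs of neighbouring genes in the induced line. A single outlying array is argued against, since on the 2D arrays, which played no part in finding these runs, each of the 8 was shifted in its 3D direction by at least 0.19 whichever 2D array was left out. A response to DPPA3 stays open for the run from ZMYND11, which shifted by -0.42 in C75 but by 0.10 in C66, with loss of DPPA3 not shown in either clone. It stays open too for the other runs, whose largest opposite shift in the knockdown or a clone was 0.0644, as no arrays of the line without doxycycline were analysed here. All 8 runs had a shift of the same sign and within 1.5 times after 4 hours in 2D, so a standing difference between the lines, such as DNA copy number, is a candidate explanation.

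The second pattern is the genes lower both with induction in 3D and in C75. The shared run is argued against as the whole cause, since 16 such genes lay outside all runs where independent lists would share 0.775. Opposite responses to gain and loss stay open for other genes, and the counts outside the runs cannot decide on them. There, 6 genes were higher with induction and lower in C75, where 0.863 would be shared (adjusted p = 2.86e-04 by Fisher's exact test). But 3 genes were higher in both, where 0.454 would be shared (adjusted p = 0.0122 by Fisher's exact test). Only 1 was lower with induction and higher in C75, where 0.408 would be shared (adjusted p = 0.361 by Fisher's exact test). An excess was thus not particular to opposite directions. Of all 26 genes shared with C75, 26.9% went opposite ways (exact 95% interval 11.6% to 47.8%), a share that the 16 genes of the pattern hold down. Against C66, 64.2% of 53 genes shared outside the runs went opposite ways (exact 95% interval 49.8% to 76.9%), which leaves opposite responses open there too. Of the 16 genes 10 were also lower after 4 hours in 2D, against 7.19% of the other 292 genes lower in 3D outside runs. The 16 include several of the largest falls in 3D, which pass a threshold more easily. A standing difference between the lines could give this share, and so could a response to DPPA3 already present at 4 hours. The share cannot tell these apart, so a standing difference stays a candidate.

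The third pattern is the lower cell-cycle lists and higher hypoxia list with induction in 3D, the latter called by camera only with the preset correlation (adjusted p = 0.0752 with an estimated correlation). Runs of neighbours are argued against for the cell-cycle part, since the G2 and mitosis median was -0.37 without the genes of the runs. A pair of arrays that deviated together, induced replicate 2 and control replicate 3 (r = 0.290 across genes), is argued against for the G2 and mitosis list alone, since its median was -0.40 without both. A step further along the difference between 3D and 2D culture stays open, with a mean correlation across genes of 0.173 over the 3 divisions of the control arrays. A biological effect of DPPA3 stays open too, since induction and line cannot be separated without arrays of the same line without doxycycline.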

How the results depend on the processing

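Leaving out the genes of neighbour runs, leaving out induced replicate 2 with control replicate 3 in 3D, and giving each clone a control array of its own were chosen after seeing the data; the other alternatives were planned. Of 735 alternative values of the main results 600 kept their direction and side of the threshold, or stayed within 1.5 times or the spread. Of 2832 values of named genes 2657 did, 172 lost the call, 3 gained it and 0 reversed by limma; 30 of 176 named results lost the call in some alternative. CA12 gained it in the knockdown with cyclic loess and array weights (adjusted p = 0.0435 and 0.0453), and MUC2 in the mean of the clones with array weights (0.0453). Unless construction is named, the cause was not tested.

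With camera's estimated correlation, the list shifts were as before and calls ended for hypoxia with induction in 3D (0.27, adjusted p = 0.0752), in 2D (0.14, 0.544) and in the knockdown (-0.15, 0.226), for S phase (0.0833, 0.304) and G2 and mitosis (0.0385, 0.252) in the knockdown, and for S phase in C66 (-0.16, 0.539). With cyclic loess, hypoxia was 0.11 in 2D (0.0791) and -0.12 in C75 (0.0252), and the knockdown and C66 shared 1 gene the same way, against 0. Without the dim genes, hypoxia in 2D was 0.14 (0.159), r of the effects in 3D and 2D was 0.514, and the knockdown shared 2 genes the same way with induction in 2D and 2 with C66, against 0 by limma. With the replicate number as a block, hypoxia was 0.14 in 2D (0.0563) and -0.0857 in C75 (0.0466).

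With array weights, changed genes were 26 in the knockdown, 546 in C66, 256 in C75 and 248 for the mean of the clones. With variances from a comparison's own arrays, they were 468 for induction in 3D, 314 in 2D, 164 in C75, 104 for the mean, 7 for the difference of effects and 562 for the control line. Without the genes of runs, fewer genes were tested and 601, 210, 126, 53, 30 and 267 changed for induction in 3D, in 2D, C66, C75, the mean and the difference between clones.

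With control replicate 1 for C66 and 2 for C75, r between clones was 0.110 and 2 genes changed the same way; with the reverse, 0.0637 and 1. By construction no control array was then shared, and fewer arrays were used.

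Leaving out 1 array gave 663 to 989 changed genes for induction in 3D, 8 to 12 in the knockdown, 89 to 120 in C66, 38 to 67 in C75, 5 to 34 for the mean, 11 to 70 for the difference of effects, 259 to 270 between clones and 875 to 1221 for the control line. Fewer arrays also lower the power. Correlations ranged from 0.414 to 0.452 for induction in 3D with 2D, -0.0977 to -0.0330 with the knockdown, -0.0994 to 0.0590 with C66 and 0.00418 to 0.151 with C75. They ranged from -0.0354 to 0.0446 for induction in 2D with the knockdown, -0.00513 to 0.138 for the knockdown with C66, 0.00548 to 0.138 with C75 and 0.290 to 0.483 between clones. Genes changed the same way numbered 1 to 3 for induction in 3D with the knockdown, 12 to 31 with C66, 19 to 52 with C75, 0 to 2 for induction in 2D with the knockdown, 0 to 1 for the knockdown with C66, 0 to 4 with C75 and 1 to 7 between clones. Hypoxia medians ranged from 0.0847 to 0.14 in 2D, -0.20 to -0.0681 in the knockdown, -0.11 to 0.0818 in C66, -0.19 to 0.0329 in C75 and -0.16 to 0.0681 for the mean. Without control replicate 2 the uncalled hypoxia median of C66 changed sign to -0.11 and passed (adjusted p = 0.0411). S phase ranged from 0.0444 to 0.13 in the knockdown, -0.21 to -0.10 in C66 and -0.14 to -0.0470 for the mean, and G2 and mitosis from 0.0550 to 0.10 in the knockdown.

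Across all genes the replicate numbers showed no clear pairing. Deviations of same-number arrays correlated at -0.209 to 0.168 over 13 pairs, 2 of them above 0.1. In groups of 2 arrays the deviations mirror each other, so both pairs of a clone give the same value (0.0940 for C66 and 0.00904 for C75). The hypoxia score was higher in replicate 1 than in replicate 2 of the knockout control (0.385 and 0.177), C66 (0.334 and 0.178) and C75 (0.255 and 0.104). DPPA3 without the transgene had a signal above only 14.6% to 38.5% of genes, so a further loss of its RNA was not detectable at this signal.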

Other observations

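The observations below rest on tests chosen after the results had been seen. The induced line and clone C75 shared the run from ZMYND11 (-0.50 in 3D, -0.45 in 2D and -0.42 in C75) and falls in NELL2, UPK1A, PLA2G2A and CST1. A hypothesis is that both lines may descend from a similar subclone of SW1222. NELL2, UPK1A, PLA2G2A and CST1 are among the 16 shared genes outside the runs. These genes gave rise to the hypothesis, so they cannot test it. No DNA measurement was used here to test the hypothesis. Other values do not go with it. The other runs found with induction in 3D had medians from -0.0969 to 0.0278 in C75. The other runs of C75 had medians from -0.0669 to 0.0569 with induction in 3D. The fall of PLA2G2A also differed between 3D and 2D in the induced line, by -1.71. Neighbouring genes' fold changes with induction in 3D correlated at r = 0.181, above the highest of 1000 shuffled orders (0.0443, permutation p = 0.000999, the smallest they can give). Every other comparison tested gave the same permutation p, with r from 0.0478 for the control line in 3D over 2D to 0.210 for induction in 2D. As all these p-values are at their floor, they cannot rank the comparisons. The values of r differed, with 0.165 in C66, 0.124 in C75 and 0.0562 in the knockdown. Such a correlation was thus not particular to the induced line. It does not tell which runs are shared between lines, so it does not test the hypothesis.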
